A study of Mus musculus with 4 samples.

How the data were processed

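Gene expression of sorted small intestinal epithelial cells was measured by droplet single-cell RNA sequencing with the 10x Genomics 3' v3.1 chemistry, per the labels' protocols. The labels name 4 libraries, each a pool of hashtagged cells of PBS-treated and IL-25-treated mice, so all 4 fall into 1 group. A treatment label of PBS on all 4 differs from their titles, which name both treatments, and 1 protocol writes IL-2 where the rest write IL-25; the titles were followed. Hashtags 301 to 305 stand for the 5 PBS parts of the small intestine and 306 to 310 for those of IL-25, per the labels, and hashtag 309 has no exact position.

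The submitters' processing notes name Cell Ranger 5.0.1, Seurat 4.3.2 and the genome build mm10, without saying which step each was used for. The deposited values are raw counts of UMIs per feature and barcode, not normalized and not filtered for cells, per the file headers and values. Such counts were analysed for the hashtag libraries of 3 libraries. Each of these 3 matrices lists 31053 features, all of gene type per the deposited feature lists, and 0 hashtags. The feature list of the hashtag library of biological replicate 2 lane 1 names 32285 genes and 10 hashtags; its matrix, and the matrices of the gene expression libraries, were not used here. Comparisons by treatment or part, which had been planned on counts summed per mouse, were therefore not made. Of the 31053 gene identifiers, 31011 (99.9%) were found in the GENCODE M21 annotation, from which coordinates were taken. How reads were filtered and how multimapped reads were counted is not given in the sources used here, so defensin genes of the Paneth list, which are near-identical copies, and the alpha and beta globins are uncertain individually.

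Totals, detected genes and the share of UMIs in 18 marker lists were computed per library, and the lanes of biological replicate 1 were also added. The lists cover enterocyte, proximal enterocyte, distal enterocyte, tuft, goblet, Paneth, enteroendocrine, stem, proliferation, type 2 response, major histocompatibility complex class II, immune, stromal, erythroid, pancreas, mitochondrial, stress and general epithelial genes. Shares have exact Clopper-Pearson 95% intervals, ratios of shares have exact conditional 95% intervals, and a count of 0 is given the limit of 3 counts. Correlations used log2(CPM + 1), computed here from the counts, over genes with at least 10 UMIs. Gene counts of library pairs were compared with a chi-square test; the one between lanes was planned, and the ones between biological replicates were added after seeing the data. Shared barcodes with at least 1 UMI were compared with the hypergeometric expectation. The plan set the list shares of biological replicates side by side without a test and named no interval for their ratios. Tests and alternatives chosen after seeing the data are named as such below. The 18 lists, the planned tests and alternatives, and the rule for named genes were fixed before the data were examined. That rule took the 10 features with most UMIs in each library, the 4 members of each list with most UMIs among those with at least 10, and the 5 highest and 5 lowest replicate ratios among features with at least 100 UMIs. The list members whose ratio interval excluded 1 are named in addition, chosen after their values were seen. Clustering required 500 barcodes with at least 500 UMIs and 200 genes, and no library had any, so doublets were not called.

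Depth limits every value. A library of 98309 to 131509 UMIs puts the limit of a count of 0 between 0.00228% and 0.00305% of its UMIs, and between 99.2% and 99.3% of the nonzero entries of a library were single UMIs. In data simulated from the real gene means and library sizes, 443 features were tested for the ratio of biological replicates. Of features changed 1.5-fold 77.0% were called in the right direction, of those changed 2-fold 99.0%, and of unchanged features 4.94% were called. The chi-square test between simulated lanes without a difference over 4442 genes gave p under 0.05 in 4.0% of draws, and independent barcodes gave a sharing ratio of 1.05. The simulated ratios and chi-square tests drew UMIs independently, without barcodes found in several libraries and without variation between mice. Their rates therefore need not hold for the real libraries.

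For the closing section, genes and barcodes were compared with barcodes of the same depth. Pairs of gene and barcode found in both libraries were set against 1000 shuffles of barcodes within 6 classes of depth per library. The share of a gene list in chosen barcodes was set against other barcodes of the same number of UMIs, in 20 classes, with the wider of a bootstrap interval of 1000 draws and a Poisson interval. Lists of lung alveolar, lung airway, neutrophil and colon genes were written after Sftpc, Scgb1a1 and S100a9 had been seen and before the other members were. A list of small intestinal absorptive genes was written with them, and its 12 genes all stand on lists fixed earlier, so UMI totals of some of them had been seen. Alternatives were barcodes with at least 10 UMIs, genes with at least 50 UMIs, a pseudocount of 10 CPM, exclusion of the 10 features with most UMIs or of mitochondrial genes, and each pair of gene and barcode counted once. Lists compared within barcodes had no gene in common, since Ang4 was left out of both the goblet and the Paneth list there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.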

Results

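Wild-type C57BL/6J mice, an inbred laboratory strain, received 500 ng of IL-25 or PBS by intraperitoneal injection 3 times a week for 4 weeks. IL-25 is a cytokine made by tuft cells that acts on group 2 innate lymphoid cells, and the title of the series names adaptation of the small intestine as its subject. Epithelial cells, sorted as EpCAM+ and CD45-, were taken from 2 mice per treatment 49 and 50 days after the last injection. Cells of each treatment and each of 5 parts along the small intestine carried an antibody hashtag, a DNA-barcoded antibody that marks the origin of a cell. The marked cells were pooled before droplet capture, so every library holds cells of both treatments. The labels name 4 libraries, made of 2 biological replicates with 2 lanes each, and do not say whether lanes are of the droplet chip or of the sequencer. Count matrices of the hashtag libraries of 3 of them were analysed here, those of biological replicate 1 lane 1, biological replicate 1 lane 2 and biological replicate 2 lane 2.

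These 3 matrices list 31053 genes and 0 hashtags. A comparison of IL-25 with PBS, or of the parts of the intestine, needs hashtag counts to tell the cells apart, so neither was made from these matrices. The values below therefore describe gene molecules, counted as unique molecular identifiers (UMIs), that were read in the hashtag libraries, for both treatments and all parts together. Biological replicate 1 lane 1 held 117859 UMIs in 66145 barcodes and 9515 genes. Biological replicate 1 lane 2 held 98309 UMIs in 58711 barcodes and 8831 genes, and biological replicate 2 lane 2 held 131509 UMIs in 70287 barcodes and 9640 genes. The median barcode carried 1 UMI in each library, the deepest carried 33, and 0 barcodes reached the 500 UMIs set as the minimum for a cell, so no cells were clustered or named. All 3 libraries belong to 1 group of pooled treatments with 2 biological replicates, so no test between groups was made. Intervals of the shares of a library and of the ratios of shares between libraries are exact 95% intervals that cover counting error only. Those of list shares in chosen barcodes, in the closing section, are the wider of a bootstrap and a Poisson interval.

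The question of which cell types the gene UMIs represent was addressed with 18 marker lists. Absorptive enterocyte transcripts led among the epithelial cell types. The enterocyte list held 5.42% of the UMIs of biological replicate 1 (95% interval 5.33 to 5.52), with both lanes added, and 5.56% of those of biological replicate 2 (5.43 to 5.68). The most abundant enterocyte genes were Apoa1, an apolipoprotein of chylomicrons and high-density lipoprotein, with 3725 UMIs over the libraries, the fatty acid binding proteins Fabp2 with 3008 and Fabp1 with 2794, and the retinol binding protein Rbp2 with 1690. Goblet cell transcripts, which encode secreted mucus components, made up 1.39% (1.34 to 1.44) and 1.36% (1.30 to 1.43) in biological replicates 1 and 2, led by Zg16 with 2010 UMIs, Tff3 with 806, Fcgbp with 421 and Spink4 with 308. Paneth cell transcripts made up 0.548% (0.517 to 0.580) and 0.517% (0.479 to 0.557), led by the defensins Defa24 with 830 UMIs and Defa30 with 342.

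Genes of both ends of the small intestine were present. The proximal enterocyte list, with Apoa1, Fabp1, Rbp2 and Apoa4 as its leading members, held 2.87% of the UMIs of biological replicate 1 and 2.95% of those of biological replicate 2. Of its 10078 UMIs, 9592 came from 6 genes that also stand on the enterocyte list, so the 2 lists are not separate evidence. The distal list held 0.760% and 0.729%. Its leading member was Fabp6, the ileal bile acid binding protein, with 1951 UMIs, followed by Clec2h with 242 and by the subunits of the basolateral bile acid exporter, Slc51a with 116 and Slc51b with 80. Genes used by epithelial cells in general held 1.55% and 1.60%, and among them were Lgals4 with 1160 UMIs, Krt8 with 840, Epcam, the surface protein used for the sort, with 791, and Pigr with 576.

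Genes of tuft cells, the epithelial source of IL-25, held few UMIs, from which no share of tuft cells can be read at this depth. The tuft list held 67 UMIs in biological replicate 1, or 0.0310% (0.0240 to 0.0394), and 41 UMIs in biological replicate 2, or 0.0312% (0.0224 to 0.0423). Of its 24 genes 14 were detected and 5 reached 10 UMIs, led by Ptprc with 22, Alox5ap with 16, Cd24a with 13 and Ltc4s with 12. Ptprc encodes CD45, which leukocytes carry, and stands on the immune list as well. Among genes that mark tuft cells more narrowly, picked after their values were seen, Dclk1 had 3 UMIs and Trpm5, Pou2f3 and Il25 had 0, which allows a share of up to 0.000863% of all UMIs. Other members of the tuft list were detected at low counts, such as Rgs13 with 6, Lrmp with 5, Hpgds with 3 and Sh2d6 with 2, and others, such as Avil and Gfi1b, had 0. The list of epithelial genes known to respond to type 2 cytokines held 0.157% (0.141 to 0.175) and 0.156% (0.135 to 0.179), with Clca1 at 194 UMIs, Itln1 at 83, Ang4 at 78 and Dmbt1 at 50. Of its 545 UMIs, 362 came from 5 genes that also stand on the goblet or Paneth list, so its share is mostly a part of theirs.

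Less abundant lineages were measured with wider intervals. Enteroendocrine genes, which encode gut hormones, held 0.0685% (0.0579 to 0.0804) and 0.0806% (0.0660 to 0.0975), led by Sct with 80 UMIs, Nts with 38, Pyy with 32 and Gip with 25. Stem cell genes held 0.0481% and 0.0494%, and Olfm4 with 93 UMIs, Cd44 with 25 and Slc12a2 with 16 were the members with at least 10. Proliferation genes held 0.161% and 0.145%, led by H2afz with 174 UMIs, Hmgb2 with 118, Tubb5 with 53 and Stmn1 with 43. Major histocompatibility complex class II genes held 0.112% and 0.109%, led by Cd74 with 216 UMIs, H2-Ab1 with 91, H2-Aa with 40 and H2-Eb1 with 18. Stress and immediate early genes held 0.429% and 0.432%, led by Jun with 251, Fos with 178, Jund with 148 and Hsp90aa1 with 124.

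Markers of cells that the sort was meant to exclude were measured in the same way. Immune genes held 0.124% (0.110 to 0.140) and 0.108% (0.0910 to 0.127) in biological replicates 1 and 2, led by Lyz2 with 223 UMIs, Cd52 with 61, Ptprc with 22 and Coro1a with 20. A neutrophil list, written after S100a9 had been seen, held 0.240% (0.219 to 0.261) and 0.221% (0.196 to 0.247), which is above the immune, tuft, stem and enteroendocrine lists. Stromal genes held 0.104% and 0.0890%, led by Vim with 117, Sparc with 63, Col3a1 with 44 and Col1a1 with 29. Erythroid genes held 0.0402% and 0.0319%, with Hba-a1 at 55, Hbb-bs at 55 and Hbb-bt at 18. The pancreas list held 4 UMIs in each biological replicate, which is 0.00185% and 0.00304%. Of the 191 UMIs of Lyz1, the Paneth lysozyme, 84 lay in barcodes that also held Sftpc, a gene of lung alveolar cells, and so did 37 of the 223 UMIs of Lyz2, so part of the Paneth and immune shares stood in barcodes with a lung transcript.

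**Figure D1:**
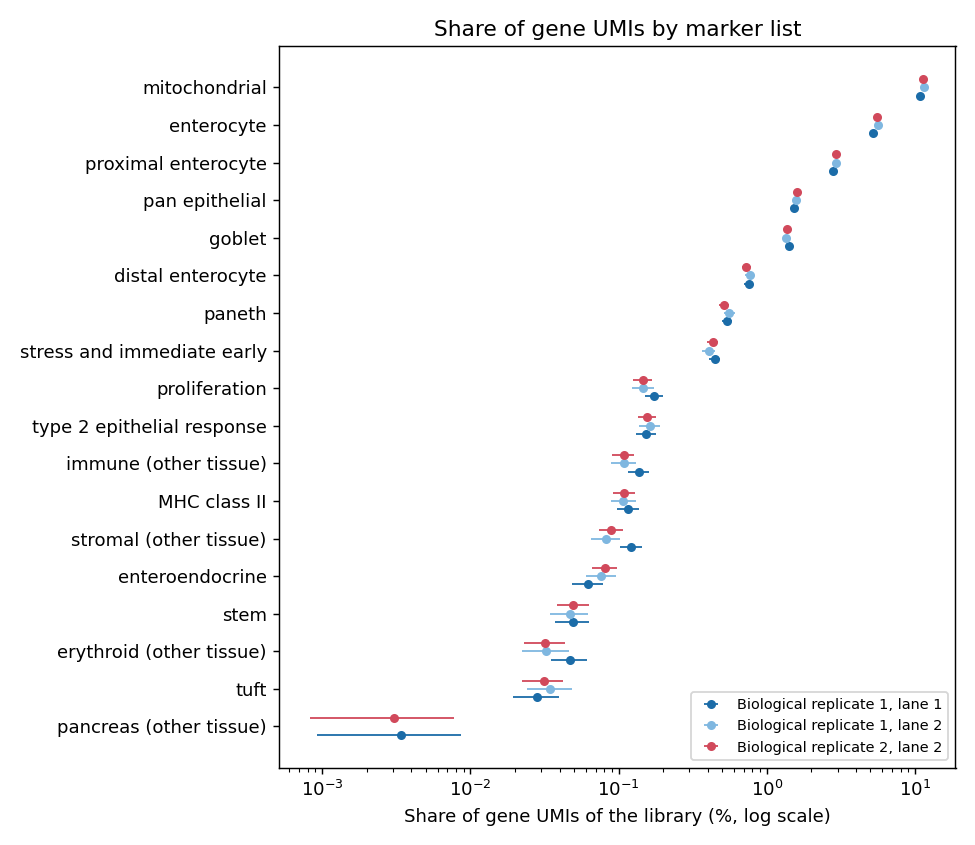
Share of the gene UMIs of each library held by each of 18 marker lists, in percent on a log scale. Points are the 3 libraries and bars are exact 95% intervals for counting error; a list with 0 UMIs in a library has no point. Mitochondrial and enterocyte genes hold the largest shares, and the tuft list stays near 0.03%.

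The single features with most UMIs were Gm42418 and mitochondrial transcripts. Gm42418, a noncoding gene on chromosome 17 from 39846958 to 39848788 (mm10) that is known to collect ribosomal RNA reads, held 4.21%, 4.47% and 4.35% of the UMIs of biological replicate 1 lane 1, biological replicate 1 lane 2 and biological replicate 2. It was followed by mt-Co3 with 7506 UMIs over the libraries, mt-Atp6 with 7219, the nuclear long noncoding RNA Malat1 with 6228, mt-Co1 with 6126, mt-Co2 with 5741 and mt-Cytb with 4047. Apoa1 (chromosome 9, 46228580 to 46230466), Fabp2 (chromosome 3, 122895072 to 122899506), Fabp1 (chromosome 6, 71199827 to 71205023) and mt-Nd4 with 2760 UMIs completed the features that were among the 10 highest in any library. The 10 highest features of each library held 17.2%, 18.1% and 17.8% of the UMIs of the 3 libraries. The mitochondrial list as a whole held 11.1% (10.98 to 11.2) in biological replicate 1 and 11.3% (11.2 to 11.5) in biological replicate 2.

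Biological replicates were then compared by the ratio of UMI shares, replicate 2 over replicate 1. For 0 of the 18 marker lists did the 95% interval of the ratio exclude 1. Barcodes found in several libraries (below) put in doubt that the biological replicates were measured separately. Ratios near 1 therefore do not show that the biological replicates are alike. The enterocyte ratio was 1.02 (0.995 to 1.05), the goblet ratio 0.983 (0.927 to 1.04), the Paneth ratio 0.944 (0.858 to 1.04), the tuft ratio 1.01 (0.665 to 1.51) and the ratio of the type 2 response list 0.991 (0.829 to 1.18). The tuft interval leaves room for a difference of 1.5 times in either direction, so a smaller difference was not detectable at this depth. The result depends on the barcodes and lanes used. In barcodes with at least 10 UMIs, the intervals of 3 lists excluded 1, with ratios of 1.34 (1.12 to 1.60) for enterocyte, 1.401 (1.08 to 1.82) for proximal enterocyte and 0.541 (0.456 to 0.642) for Paneth genes. The ratios of distal enterocyte, stress and stem genes there were 1.69, 1.62 and 0.279, with intervals that included 1. Only 243, 126 and 488 barcodes of the 3 libraries had at least 10 UMIs, and genes of a list recurred together in barcodes (below). The intervals take UMIs as independent, so they may be too narrow there, and few barcodes may carry a ratio. In barcodes found in a single library the tuft ratio was 0.561, with an interval that included 1, and the proximal enterocyte interval excluded 1 at 1.09. The mitochondrial interval excluded 1 at 1.08 without the 10 features with most UMIs, 5 of which are mitochondrial genes themselves, and at 1.02 (1.0007 to 1.04) without Gm42418, AY036118 and Lars2, close to the ratio of 1.02 (0.9998 to 1.04) with all features. With lane 2 of biological replicate 1 left out, the intervals of 5 lists excluded 1, with ratios of 1.06 for enterocyte, 1.06 for proximal enterocyte, 1.05 for mitochondrial, 0.790 for immune and 0.733 for stromal genes.

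Among 443 features with at least 100 UMIs, the interval of the replicate ratio excluded 1 for 27, or 6.09%, 12 higher and 15 lower in biological replicate 2, where counting error alone gives 5%. The highest ratios were those of Krt20, a keratin of mature surface epithelium, at 1.60 (1.22 to 2.10), Cyp4f14, a fatty acid hydroxylase, at 1.55 (1.03 to 2.33), the AP-1 subunit Junb at 1.53 (1.03 to 2.27), the myosin light chain Myl12b at 1.504 (1.02 to 2.21) and Ndufa5 of respiratory complex I at 1.48 (1.03 to 2.11). The lowest were Ms4a10 at 0.598 (0.373 to 0.932), Mttp, the lipid transfer protein needed for chylomicron assembly, at 0.618 (0.427 to 0.881), the proteasome subunit Psmb1 at 0.621 (0.397 to 0.94997), and Iqgap2 and Gsto1, both at 0.662 (0.415 to 1.03). The ratios of Junb and Psmb1 changed sides, to 0.811 and 1.05, in barcodes found in a single library, and those of Junb and Ms4a10 changed sides, to 0.744 and 1.49, in barcodes with at least 10 UMIs. On the marker lists, the interval excluded 1 for Krt20 and Mttp of 26 enterocyte genes and for Defa24 at 0.828 (0.714 to 0.958) of 12 Paneth genes with at least 10 UMIs. It also did so for Col3a1 at 0.365 (0.147 to 0.799) of 8 stromal genes, for mt-Nd4 at 1.10 (1.02 to 1.19) of 13 mitochondrial genes and for Junb of 16 stress genes. On the other lists fixed earlier it did so for no member with at least 10 UMIs, among them 12 goblet, 5 tuft and 13 general epithelial genes. Defensins such as Defa24 are uncertain individually.

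The lanes of biological replicate 1 also differed in composition. Lane 2 held more enterocyte transcripts, with a ratio to lane 1 of 1.08 (1.04 to 1.12), more proximal enterocyte transcripts at 1.06 (1.01 to 1.11) and more mitochondrial transcripts at 1.06 (1.03 to 1.08). Lane 2 held fewer stromal transcripts at 0.679 (0.511 to 0.898). Lists written after the data had been seen were also lower in lane 2, at 0.659 (0.575 to 0.755) for lung alveolar and 0.660 (0.549 to 0.793) for neutrophil genes. For 4 of the 18 lists fixed earlier the interval excluded 1, and for 28 of 443 features, or 6.32%, where counting error alone gives 5%. The enterocyte and proximal enterocyte lists have most of their proximal UMIs in common and are not separate evidence.

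**Figure D2:**
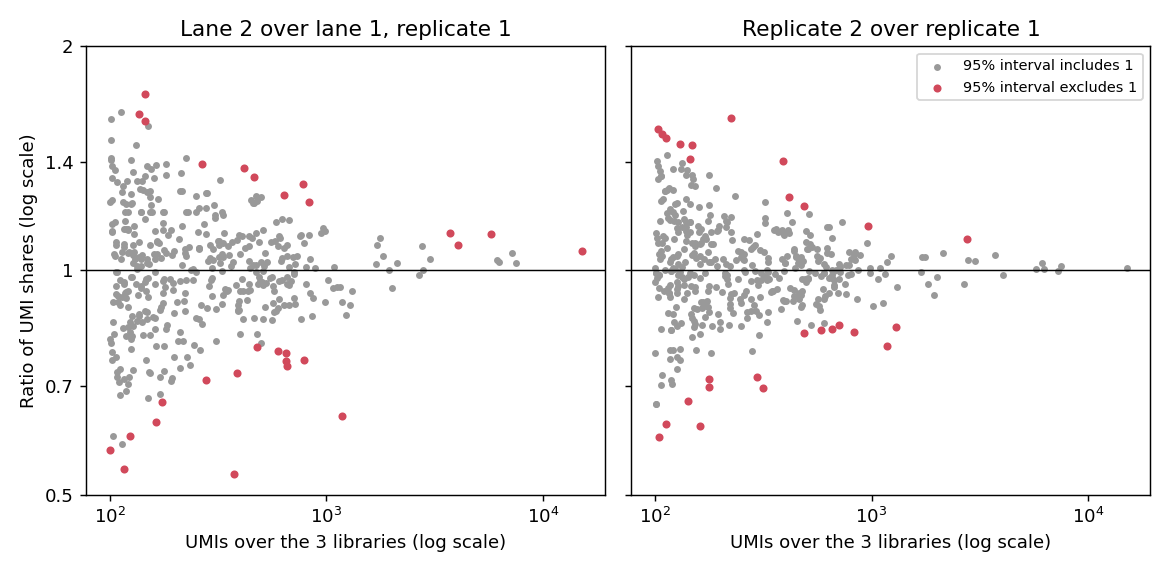
Ratio of UMI shares of 443 features with at least 100 UMIs, on log scales, against the UMIs of the feature over the 3 libraries. Each point is a gene; the 28 and 27 features whose 95% interval excludes 1 between lanes and between biological replicates are in red, and their spread narrows as UMIs increase.

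Agreement across genes was measured to ask whether biological replicates differ more than lanes of the same pool. Across 4442 genes with at least 10 UMIs, Pearson's r of log2(CPM + 1) was 0.799 between the lanes of biological replicate 1 (Spearman's rho 0.740), 0.844 between lane 1 and biological replicate 2 (rho 0.755) and 0.811 between lane 2 and biological replicate 2 (rho 0.755). Genes are not independent replicates, and these values give no test across samples. The lanes were also the libraries with fewest UMIs, 117859 and 98309 against 131509 in biological replicate 2, and low counts reduce r. The order of r therefore does not show that lanes differ more than biological replicates. The lanes of biological replicate 1 differed by slightly more than sampling noise, with a chi-square of 1.05 per degree of freedom (chi-square test, p = 0.00761). The chi-square of lane 1 against biological replicate 2 was 1.03 per degree of freedom (chi-square test, p = 0.108), and that of lane 2 against biological replicate 2 was 0.984 (chi-square test, p = 0.767). With genes of at least 50 UMIs only, the lanes differed at 1.201 per degree of freedom (chi-square test, p = 1.87e-05) and lane 1 also differed from biological replicate 2, at 1.13 (chi-square test, p = 0.00319). The chi-square test takes libraries as independent, which barcodes found in several libraries (below) put in doubt, so a value near 1 does not show that biological replicates are alike. Lane 2 and biological replicate 2 had 1511 pairs of gene and barcode in common and were not copies of each other. No mean over libraries was formed from them.

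Barcodes were compared between libraries to ask whether the wells were separate. The same barcodes carried UMIs in different libraries far more often than separate draws from the list of 6794880 barcodes allow. Lanes 1 and 2 of biological replicate 1 had 27083 barcodes in common where 572 were expected, a ratio of 47.4 (46.8 to 48.0). Lane 1 and biological replicate 2 shared 30750 barcodes where 684 were expected, a ratio of 44.9 (44.4 to 45.4). Lane 2 and biological replicate 2 shared 28293 where 607 were expected, a ratio of 46.6 (46.0 to 47.1). The exact hypergeometric test gave log10 p values of -39771, -44745 and -41466. Of 130183 barcodes with a UMI in any library, 16.3% were in all 3, and 72.4%, 73.0% and 72.3% of the UMIs of the 3 libraries lay in barcodes found in another library. The libraries were therefore not independent samples of barcodes, and the intervals of ratios between them do not account for this. If the libraries hold reads of the same cells, ratios near 1 between biological replicates would follow whatever the mice.

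**Figure D3:**
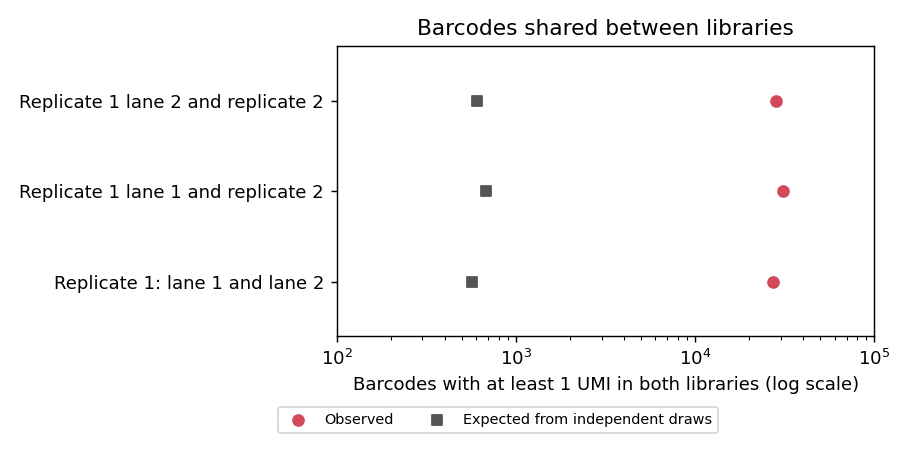
Number of barcodes with at least 1 UMI in both libraries of a pair, on a log scale, for the 3 pairs of libraries. Circles are observed numbers (27083 to 30750) and squares are numbers expected from independent draws (572 to 684).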

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

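Lung, neutrophil and colon genes are given here because their UMIs exceed the limit that a count of 0 allows in libraries of sorted small intestinal epithelium, with no control library to set them against. The lists were written after Sftpc had been seen. The tests of free RNA, of lung cells in the suspension and of another library replaced earlier ones that could not tell these explanations apart, and were chosen when their values or closely related ones were known. The alveolar list held 1406 UMIs over the 3 libraries, of which Sftpc, the surfactant protein of alveolar type 2 cells, gave 1182, Sftpa1 67, Slc34a2 45 and Cxcl15 32. The airway list held 86, of which the club cell gene Scgb1a1 gave 79. The neutrophil list held 808, led by S100a9 with 373 and S100a8 with 267, although neutrophils carry CD45 and the sort would remove them. The colon list held 99, led by Car4 with 54 and Slc26a3 with 29, genes that the small intestine also expresses. Of the 12 alveolar, 8 airway, 9 neutrophil and 6 colon genes, 0 stand on a list fixed earlier, whereas all 12 small intestinal absorptive genes used below do. The alveolar share of biological replicate 2 was 0.833 times that of biological replicate 1 (0.744 to 0.932), and this rests on lane 1, without which the ratio was 1.07. Between lanes 2 and 1, the ratios were 0.659 (0.575 to 0.755) for alveolar and 0.660 (0.549 to 0.793) for neutrophil genes.

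Sftpc UMIs came with those of other alveolar genes, which held a share of the remaining UMIs of Sftpc barcodes 166 times that of barcodes of equal depth, so misplaced reads of Sftpc alone do not account for them. Absorptive intestinal cells expressing Sftpc are argued against by small intestinal absorptive genes at 0.0206 times the matched share in those barcodes. Other intestinal epithelial cells are not covered by that list, which was also low, at 0.242, in barcodes with Zg16 in 2 or more libraries. Free RNA spread over all barcodes would hold these genes at the matched share. It is argued against by the upper 95% bound of their ratio in Sftpc barcodes, 0.0527. Lung cells carried in the sorted suspensions and reads of another library of lung cells cannot be told apart: the lower 95% bound of the alveolar ratio, 139, speaks for lung transcripts in both cases. At equal depth, observed over expected recurrences of Sftpc in the same barcodes of both biological replicates were 0.923 times those of the goblet gene Zg16 (0.770 to 1.11). In ratios added later, they were 3.37 times those of Fabp6 (2.66 to 4.3004) and 3.596 times those of Reg3b (2.55 to 5.19). They were 11.01 times those of Apoa1 (8.66 to 14.1) and 7.09 times those of Apoa4 (3.67 to 15.7). Those of the airway gene Scgb1a1, also added later, were 8.58 times those of Zg16 (4.74 to 14.4), with 15 observed and 0.0573 expected. The expected number follows how many barcodes hold the gene, so abundance enters these ratios. A barcode can count for each lane of biological replicate 1, and the 232 recurrences of Sftpc lay in 182 barcodes. The intervals do not account for such repeats. The outcome depends on the gene compared and leaves the source open. Free RNA within a lung library was not tested, and EpCAM+ and CD45- alveolar cells would pass the sort. Apart from absorptive intestinal cells expressing Sftpc, no biological explanation was tested.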

How the results depend on the processing

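Barcodes found in a single library or in 2 or 3 libraries, leaving out a lane, leaving out Gm42418, AY036118 and Lars2 or lung genes, chi-square tests between biological replicates, the chi-square with each pair of gene and barcode counted once, and the counts of lists and features whose interval excludes 1 were chosen after seeing the data. No paired analysis was possible because the 3 matrices used pool both treatments and hold no hashtags. For the same reason the other settings set out for hashtag UMIs, the IL-25 share, the parts of the intestine, IL-25 against PBS and expression along the intestine were not run. The tuft, enteroendocrine, class II, immune, stromal, erythroid, neutrophil and colon lists had too few UMIs for a ratio in barcodes with at least 10 UMIs, and mitochondrial genes have none without themselves.

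Pearson's r for the lanes, lane 1 with biological replicate 2 and lane 2 with biological replicate 2 rose to 0.957, 0.965 and 0.965 with genes of at least 50 UMIs and to 0.867, 0.888 and 0.877 with a pseudocount of 10 CPM, both of which reduce the weight of low counts. Lane 1 against biological replicate 2 reached a chi-square of 1.13 per degree of freedom with genes of at least 50 UMIs. In barcodes with at least 10 UMIs, 2869, 1506 and 5881 UMIs remained, sharing stood at 9765, 5100 and 6851 times chance, and the ratios of biological replicate 2 to 1 were 1.34 for enterocyte, 1.401 for proximal enterocyte, 1.69 for distal enterocyte, 0.783 for goblet, 0.541 for Paneth, 0.279 for stem, 0.7002 for type 2 response, 1.07 for mitochondrial, 1.62 for stress and 1.34 for general epithelial genes. There, 3 lists (enterocyte, proximal enterocyte and Paneth) and 14 features had intervals that exclude 1, against 0 and 27. These intervals take UMIs as independent, although the UMIs lay in 243, 126 and 488 barcodes, so they may be too narrow. In barcodes of a single library, the ratios were 1.09 for proximal enterocyte, 0.561 for tuft, 1.05 for goblet, 0.737 for stem, 0.684 for proliferation and 0.590 for stromal genes, with 1 list (proximal enterocyte) and 15 features excluding 1. The mitochondrial list, at 1.08 without the 10 features with most UMIs, was the 1 list to exclude 1 there, with 5 of its genes among those left out, and at 1.02 the 1 list without Gm42418, AY036118 and Lars2. With either lane left out, the ratio ran from 0.985 to 1.06 for enterocyte, from 0.733 to 1.08 for stromal, from 0.991 to 1.05 for mitochondrial and from 0.704 to 1.07 for alveolar genes, and 0 to 5 lists excluded 1. Junb turned to 0.744 in barcodes with at least 10 UMIs and 0.811 in barcodes of a single library, Ms4a10 to 1.49 in the former and Psmb1 to 1.05 in the latter. Beyond fewer UMIs and fewer libraries, the cause was not tested. The interval of the tuft ratio, 0.665 to 1.51, shows the size of change that this depth leaves open.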

Other observations

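All tests here except that of colon cells, and all the values of genes recurring in barcodes, were chosen after barcode sharing had been seen. The test of free RNA for Zg16 replaced an earlier one that could not exclude it, and was chosen when related values were known. In barcodes found in 2 libraries, genes of a list recurred, where a gene repeating itself also counts. A barcode found in all libraries can count for several pairs of libraries, which the intervals do not account for. Goblet genes in a barcode of one library went with goblet genes in the same barcode of another 18.2 times as often as chance gives at that depth (17.1 to 19.4), Paneth with Paneth genes 27.6 times (23.0 to 32.8), enteroendocrine with enteroendocrine genes 164 times (122 to 217), and proliferation with proliferation genes 5.54 times (3.17 to 9.002). Goblet and Paneth genes went together 4.82 times as often (3.93 to 5.85), with Ang4, a member of both lists, left out. Which genes carry this excess was not tested. Between different genes of a list, a barcode can also count for several pairs of genes. The ratio there was 17.4 for goblet, 28.5 for Paneth, 161 for enteroendocrine, 5.28 for proliferation and 86.8 for neutrophil genes. The ileal genes Fabp6 and Slc10a2 recurred at 8.72 times (7.38 to 10.2), with 151 of 152 cases from a gene repeating itself, and the proximal genes Apoa4 and Lct at 2.98 times (1.49 to 5.33), with 11 of 11, so no recurrence of different genes can be read from these. Proximal with distal genes met at 0.270 times the expected number (0.0736 to 0.691). Tuft genes recurred in 0 barcodes where 0.0414 were expected, too few to read. Neutrophil genes recurred with neutrophil genes 83.0 times as often as by chance (69.7 to 98.2), and goblet with alveolar genes 0.0652 times (0.0135 to 0.191). Paneth with alveolar genes met 8.57 times as often (6.97 to 10.4), in 99 cases, and without Lyz1 in 0 cases where 8.17 were expected.

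Barcode sharing itself was weighed against the explanations that could produce it. Unrelated reads gathered by a few favoured barcodes would repeat pairs of gene and barcode about as often as after shuffling, but such pairs were found in both libraries at least 2.62 times as often. Droplets of 1 biological replicate read in both lanes would raise sharing between lanes. Over all barcodes, sharing between lanes was 1.04 times the mean of that between biological replicates, which argues against such droplets. In barcodes with at least 10 UMIs it was 1.63 times, between the limits of 1.5 and 2 set for the test. That ratio also depends on the number of such barcodes, 243 and 126 in lanes 1 and 2 and 488 in biological replicate 2. Of those of lane 2, 34.9% also had at least 10 UMIs in lane 1 and 49.2% in biological replicate 2. For these deeper barcodes the ratio therefore cannot decide, and such droplets stay open. Reads of common source libraries assigned to all 3 libraries may be the source, with repeated pairs up to 2.78 times the shuffled number. This is the same measure that was set against favoured barcodes, so it is not separate evidence for common source libraries. Which libraries those would be, whether reads crossed at the index or during preparation, and any biological explanation were not tested.

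Zg16, a goblet cell lectin, repeated in the same barcodes of different libraries at least 30.1 times as often as by chance at their depth. In the barcodes with Zg16 in 2 or more libraries, other goblet genes such as Tff3, Muc2 and Clca1 held 32.8 times the matched share (29.0 to 36.7), consistent with goblet cells behind these barcodes. Free RNA spread over all barcodes would hold small intestinal absorptive genes at the matched share, and their ratio was 0.242 with an upper 95% bound of 0.392. Colon genes had 0 UMIs there where 0.440 were expected, so the ratio of 0 has an upper bound of 8.38 and colon cells cannot be told apart from those of the small intestine, also because the list holds absorptive genes. Of these 271 barcodes, 212 had Zg16 in both biological replicates and 59 in the lanes of biological replicate 1 alone, and which pool the cells came from was not tested.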
